A study of Mus musculus with 4 samples.

How the data were processed

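Gene expression was measured in 4 samples of mouse B lymphocytes, 1 array per sample. Per the labels' protocols, cell suspensions were made from spleens, thymi and lymph nodes of C57BL/6 mice, and B cells were sorted with an antibody to B220 (CD45R), a surface protein of B cells. Total RNA was extracted with Tri-reagent and labelled with biotin for Affymetrix arrays. The samples form 4 groups of 1, taken from the sample titles: wild type or Tilcara, each non-stimulated or stimulated. Tilcara is described in the labels as a mouse mutant of PKCbeta (protein kinase C beta). Stimulated cells were kept for 4 hours with PMA, a phorbol ester, at 10 ng/mL and with the ionophore A23187, which lets calcium in, at 1 µM. The series describes its samples as 4 biological samples, and how many mice gave cells to each is not given in the sources used here.

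The deposited table held log2 signals of 41345 probe sets. The authors made them with RMA, per the submitters' processing notes, which name no version; RMA corrects background, normalizes quantiles between arrays and summarises probes into 1 log2 value per probe set. The software, its settings and the annotation used by the authors are not given in the sources used here. The array medians lay between 3.73 and 3.79, as quantile normalization leaves them. Such normalization assumes similar distributions in all arrays, so a change in the total RNA per cell after stimulation cannot be seen in these values.

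Gene symbols came from the platform annotation. 23521 probe sets had 1 symbol, 1814 had several and 16010 had none; only those with 1 symbol were named. The gene IDs of 23328 of them were found in the RefSeq gene table of the mouse, and no symbol needed updating. The named probe sets stood for 22180 genes, of which 1082 had several; the probe set with the highest mean over the 4 arrays stood for its gene. A gene was used if its highest value was at least 3.83, the median of all values of named probe sets, which left 12456 genes. No genome build was named, so gene positions are not given.

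With 1 array per group there is no spread between replicates. Each of 5 comparisons (stimulated minus non-stimulated in each genotype, Tilcara minus wild type in each state, and the difference between both responses) was therefore a difference of log2 values with no test. Genes were counted at an absolute difference of at least 1, which is 2-fold. For a gene list, the median difference of its measured members was set against 10000 random lists of the same size matched on mean signal in 20 bins. Size of response was not matched. A list is said to stand apart from random lists where its median lay outside their central 95%; this describes these 4 arrays and is no p-value for the conditions. In addition, limma fitted stimulation and genotype together over the 4 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. In that fit the genotypes serve as the 2 samples of each stimulation state, and the 1 residual degree of freedom is the difference between the responses, so a response that differs by genotype counts as error. Of the comparisons, only the main effects of stimulation and genotype were tested. The words rose and fell are used for limma's calls. The slope of the Tilcara response on the wild-type response was a total least squares line through the origin, over genes whose mean response was at least 1 in size.

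The tests, the alternatives, the 30 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Prkcb and the other PKC genes; in each comparison the 6 genes with the largest increase and the 6 with the largest decrease of at least 1, without predicted genes, small RNAs and immunoglobulin or T cell receptor segments; up to 4 members of each list with the largest difference in that comparison; and every member of the lists for sex or other cells that differed by at least 1. Other genes named in the text were chosen after their values were seen. The 8 lists that answer the comparisons were NF-kB targets and regulators, immediate-early and MAPK-induced genes, calcium and NFAT-induced genes, activation surface molecules, cytokines and chemokines, quiescence and homing genes, ribosome biogenesis, and glycolysis and growth metabolism. Lists of B cell programmes covered B cell identity, MHC class II presentation, PKC and B cell receptor signalling, marginal zone, B-1, germinal centre, plasma cell, and immature B cell genes. Further lists covered cell cycle, interferon response, heat shock, unfolded protein and amino acid stress, p53 and apoptosis, and housekeeping genes. Markers of T cells, thymocytes, macrophages, neutrophils, dendritic cells, NK cells, erythroid cells and sex were also listed. Another 4 lists, named second lists in the closing section, were written after the comparisons had been seen.

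The alternatives were centring each array on its median, cyclic loess between arrays, the mean over a gene's probe sets, no filter or a filter at the 75th percentile, a threshold of 1.5-fold, lists without shared members, a variance trend in limma, and other selections of stimulated genes. One alternative, leaving out neutrophil and macrophage genes, was added after seeing the data.

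The procedures were tested on simulated data with normal noise, independent between genes. All genes of a quartile of mean signal had the same SD, taken from the difference of responses. Noise that differs between genes of a quartile was left out, and limma called 5576 genes for stimulation in the data. The rates below therefore need not hold for the fit reported. For the main effect of stimulation, with 12456 genes of which 200 were changed, limma called 8.0% of genes changed by 0.5 log2 units, 84.0% of those changed by 1 and 100.0% of those changed by 2. It called 9 of the 12256 unchanged genes for stimulation, and 2 of 12456 for genotype, where no gene was changed. For the difference of responses, 4.0% of 200 unshifted lists of 20 genes stood apart from random lists, as did 63.0% of lists shifted by 0.3 and 99.5% of lists shifted by 0.5. These lists were drawn at random and their genes varied independently. They do not show how often a list of genes that vary together would stand apart. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Probe sets without a single symbol were left out of all lists; 9915 of them reached the same signal floor.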

Results

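Expression was measured in B lymphocytes sorted by B220 from wild-type mice and from Tilcara mice, described as a mutant of PKCbeta, the product of Prkcb. PKCbeta is a kinase that links the B cell receptor to NF-kB, a family of transcription factors. The cells were either not stimulated or kept for 4 hours with PMA, a phorbol ester that activates PKC enzymes, and A23187, an ionophore that raises cytosolic calcium. Together these drugs act downstream of the antigen receptor. The 2 × 2 design asks how B cells respond and how the mutant differs in each state. Each of the 4 groups was 1 array with no replicate, so a difference between groups is a difference between single arrays. Signals are RMA values on a log2 scale, where a difference of 1 is 2-fold, and 12456 genes were used. A fold, and the rank it gives, is approximate wherever either signal lies below the signal floor of 3.83. Across all probe sets, which are not independent replicates, Pearson's r was 0.978 between the non-stimulated arrays and 0.981 between the stimulated arrays, against 0.916 to 0.927 between states. No 2 arrays shared more than 0.709% of their values.

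Prkcb itself (probe set 17482766) had nearly equal signals in both genotypes, 9.42 in wild type and 9.39 in Tilcara without stimulation, and 7.28 and 7.27 with it. The labels describe a mutant and not a deletion, so this transcript level checks nothing about the genotype labels. Over both genotypes Prkcb fell with stimulation (limma, log2 change −2.13, SE 0.15, adjusted p = 0.00156). Prkcd and Prkce, for PKC delta and epsilon, also fell, with limma log2 changes of −0.99 and −1.32. Prkci, for the atypical PKC iota, rose by 2.12. Prkca read 5.14 in both non-stimulated arrays, 5.70 in stimulated wild type and 4.84 in stimulated Tilcara. Prkcq read between 3.77 and 4.41 and Prkcz between 3.67 and 4.74 in the 4 arrays, and Prkch stayed below the signal floor.

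In wild-type B cells, stimulation gave very high signals of secreted factors and of the high-affinity interleukin-2 receptor chain. Il2 (probe set 17404880), a T cell growth factor, was 208-fold higher, the chemokines Ccl4 and Ccl3 were 94.6-fold and 60.9-fold higher, and Il10 (probe set 17216990), an anti-inflammatory cytokine, was 74.0-fold higher. Il2ra was 69.1-fold higher, and Ifi202b, an interferon-inducible gene, 83.3-fold higher. The non-stimulated signals of Il2, Ifi202b and Il10, at 2.08, 2.20 and 3.31, lay below the floor. Among the lowest genes relative to the non-stimulated array were Trim34a (74.4-fold lower), Fcrla, an Fc receptor-like gene of B cells (49.4-fold), Rnase6 (43.5-fold), the heparanase gene Hpse (43.0-fold) and Trim30b (39.9-fold). The largest decrease, 76.1-fold, was that of S100a8, an abundant neutrophil transcript that stood at 9.0 in the non-stimulated wild-type array and at 2.75 after stimulation. By size, 1666 genes were at least 2-fold higher and 1979 at least 2-fold lower in the stimulated wild-type array.

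Growth and activation lists were higher together in wild type. All 24 measured ribosome biogenesis genes were higher, with a median log2 difference of 2.20, led by Noc4l (3.12), Nolc1 (3.11), Polr1b (3.10) and Rrp9 (2.80). The list of glycolysis and growth metabolism had a median of 1.43, with the amino acid transporter gene Slc7a5 at 4.19, the folate enzyme genes Mthfd2 at 3.86 and Shmt2 at 3.21, and the spermidine synthase gene Srm at 3.18. Calcium and NFAT-induced genes had a median of 1.83; beside Il2, the orphan receptor genes Nr4a3 and Nr4a2 were higher by 5.44 and 3.81, and Rgs1 by 3.74. Cytokines and chemokines had a median of 1.75, with 12 of 19 at least 2-fold higher. Activation surface molecules had a median of 1.10; besides Il2ra they included Sema7a (3.43), Cd274, which encodes PD-L1 (2.57), and the costimulator Cd86 (2.56). NF-kB targets and regulators had a median of 0.90, with Gadd45b (3.47), the survival gene Bcl2l1 (2.87), the feedback inhibitor Tnfaip3 (2.78) and Irf1 (2.04) highest. Each of these 6 medians stood apart from random lists, but that of NF-kB targets was 0.72 and inside the random range when members shared with other lists were left out. Immediate-early and MAPK-induced genes had a median of 0.28, inside the random range of −0.35 to 0.51. Their members went both ways, 10 at least 2-fold higher and 7 at least 2-fold lower, with Fosl2 (3.66), Egr2 (3.53), Atf3 (3.53) and Spry1 (3.16) moving most.

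Resting and B cell lists were lower. Quiescence and homing genes had a median of −1.58 in wild type, led by Txnip (−4.63), the cannabinoid receptor gene Cnr2 (−4.56), S1pr1, which guides lymphocyte egress (−4.48), and Klf2 (−3.21). B cell identity genes had a median of −2.95, and 15 of 19 were at least 2-fold lower, among them Fcrla (−5.63), Cd22 (−4.78), Cd79b of the antigen receptor complex (−4.43) and Vpreb3 (−3.87). MHC class II presentation had a median of −2.37, from the accessory chains H2-Oa (−4.33), H2-DMb1 (−3.90) and H2-DMa (−3.53) and the transactivator Ciita (−2.88). The class II chains H2-Aa, H2-Ab1 and H2-Eb1 differed by −0.35, −0.44 and −0.32. PKC and B cell receptor signalling genes had a median of −1.18, with Ptpn6 (−4.10), Syk (−3.95), Rasgrp1 (−3.42) and Btk (−3.20), and interferon response genes one of −1.12, although Cxcl10, a member of that list, was higher by 5.01. Each of these 5 medians lay below the random range.

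Transcripts of other cells moved in this comparison too, as measured facts beside the counts above. S100a8 and S100a9 were lower by 76.1-fold and 17.5-fold, and the macrophage and neutrophil gene Lyz2 by 6.53-fold; the median of the neutrophil list was −0.59, inside the random range of −0.63 to 0.53, and −0.54 without a filter on low signals, below the range. The T cell genes Cd3g (−1.94), Cd3d (−1.81) and Cd8b1 (−1.24), the macrophage gene Adgre1 (−1.83), Siglech of plasmacytoid dendritic cells (−1.87) and Cd1d1 (−1.64) were also lower. Cd2 of the T cell list was lower too (−3.61, from a signal of 9.40), but mouse B cells also express it. NK cell markers had a median of −1.15, below the random range, with Klrd1 at −2.40, Klrk1 at −1.77, Prf1 at −1.31, Gzma at −1.23, Ncr1 at −1.19 and Klre1 at −1.12. Cebpb and Cox6a2 were higher, by 1.09 and 1.45. Without the genes of the neutrophil and macrophage lists, an alternative added after seeing the data, 1664 genes were at least 2-fold higher and 1971 lower.

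In Tilcara B cells, stimulation again gave high signals of receptors and chemokines. The tetraspanin gene Cd63 was 62.7-fold higher, Il2ra 61.9-fold, Ccl4 49.3-fold, the plasminogen activator gene Plau 45.4-fold, the interleukin-1 decoy receptor gene Il1r2 43.3-fold and Ccl3 41.7-fold; Cd63 (2.17) and Il1r2 (2.42) lay below the floor without stimulation. The largest decreases were those of AB124611 (50.7-fold), Tmem108 (48.8-fold), Hpse (39.1-fold), Pld4 (38.6-fold), the DNA-sensing adaptor Sting1 (38.3-fold) and the costimulatory ligand Icosl (37.7-fold). The other probe sets of Tmem108 and Hpse differed less, by −2.03 and −3.32. In all, 1481 genes were at least 2-fold higher and 1783 at least 2-fold lower.

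The lists of growth genes had medians in Tilcara close to or above those in wild type. Ribosome biogenesis had a median of 2.13, led by Polr1b (3.19), Nolc1 (2.87), Noc4l (2.81) and Rrp9 (2.65), and glycolysis and growth metabolism one of 1.72, led by Slc7a5 (4.47) and Mthfd2 (4.43). Calcium and NFAT-induced genes had a median of 2.10, with Nr4a2 (4.60), Nr4a3 (4.48), Il2 (4.17) and Egr2 (3.74). Activation surface molecules had a median of 0.71, above the random range; after Il2ra came Sema7a (3.57), Cd86 (2.64) and Il4ra (−2.20). NF-kB targets had a median of −0.10, inside the random range of −0.31 to 0.64, with a mean of 0.00 of the other sign and 5 members at least 2-fold higher and 5 lower; Cd40 (−2.22), Irf1 (1.93), Birc3 (−1.88) and Gadd45b (1.69) differed most. The cytokine list had a median of 0.31, inside the random range of −0.40 to 0.43 but outside it without a filter on low signals, although Ccl4, Ccl3, Cxcl10 (4.45) and Ltb (−4.62) differed strongly; its mean was 1.06. The median of the immediate-early list was −0.06 while its mean was 0.27, so these differ in sign, and its most different members were Egr2, Fosl2 (3.62), Atf3 (3.07) and Spry1 (2.97). Quiescence genes had a median of −1.70, B cell identity genes −2.58, MHC class II genes −2.01, PKC and B cell receptor signalling genes −1.15 and interferon response genes −1.04, and each lay below the random range. Cnr2 (−3.97), Il7r (3.83), Cd22 (−4.76), Spib (−3.86), H2-DMb1 (−4.06), Syk (−3.97) and Ddx58 (−3.84) were among their most different members.

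Markers of other cells in the Tilcara arrays included Klk1, a plasmacytoid dendritic cell gene in the list used, which was lower by 19.9-fold from a non-stimulated signal of 6.41. S100a8 (−1.45), S100a9 (−1.62), Cd2, which B cells share (−4.04), Cd1d1 (−1.73) and Siglech (−1.64) were lower, and Cd68 (1.39), Hmox1 (1.23), Cebpb (1.00) and the carbonic anhydrase gene Car2 of the erythroid list (1.38) were higher. NK cell markers had a median of −1.07, with Klrd1 (−2.49), Gzma (−2.11), Klrk1 (−1.69), Klre1 (−1.36), Ccl5 (−1.09) and Nkg7 (−1.06).

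**Figure D1:**
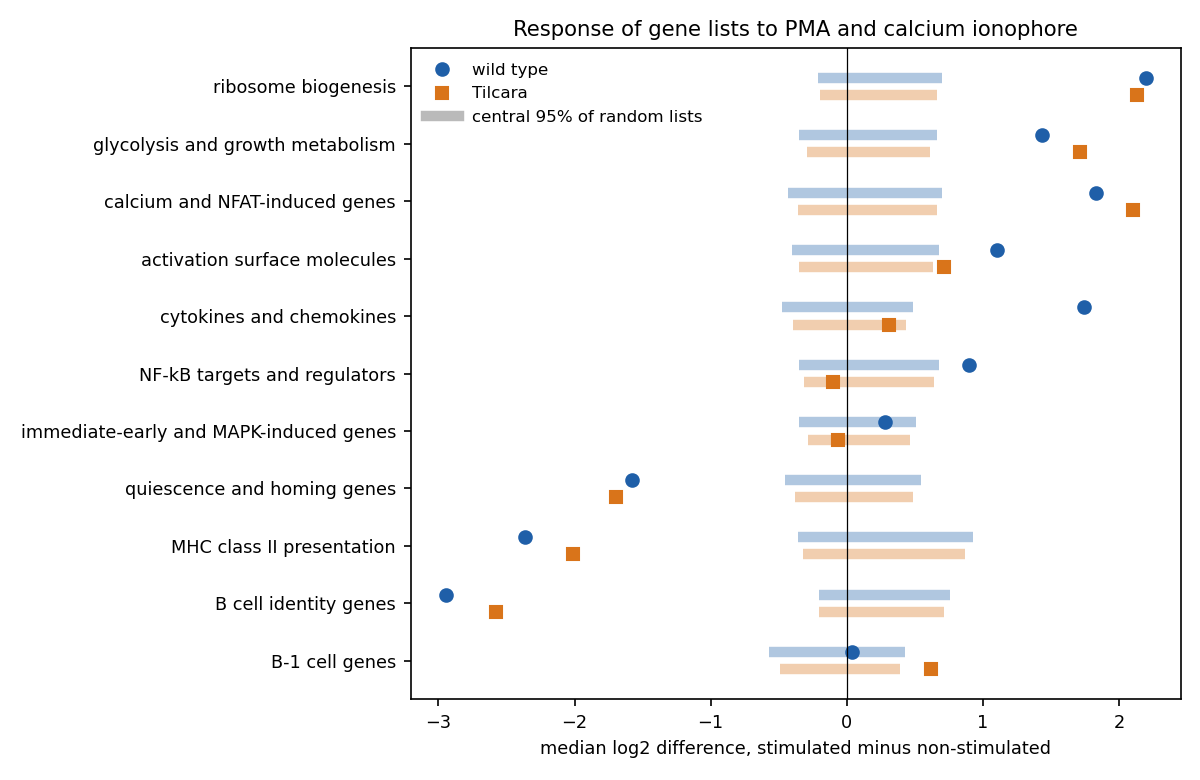
Median log2 difference, stimulated minus non-stimulated, of 11 gene lists in wild type (circles) and Tilcara (squares), 1 array per group, with bars for the central 95% of 10000 random lists matched on signal. Ribosome biogenesis lies at 2.20 and 2.13, whereas NF-kB targets lie at 0.90 in wild type and −0.10 in Tilcara.

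Taking both genotypes as the 2 samples of each state, limma called 2740 genes that rose and 2836 that fell with stimulation, and 6612 genes had an unadjusted p under 0.05. Il2ra (log2 change 6.03, SE 0.15, adjusted p = 0.00109), Plau (5.67, SE 0.17), Ccl3 (5.66, SE 0.19) and Cxcl10 (4.73, SE 0.20) rose, and Hpse (−5.36, SE 0.15), Sting1 (−5.23, SE 0.15), Cd22 (−4.77, SE 0.15) and Syk (−3.96, SE 0.15) fell. Il2 rose by 5.94 with an SE of 0.85 (limma, adjusted p = 0.00707), the wide SE reflecting its unequal responses. S100a8, at −3.85 with an SE of 1.15, did not pass (limma, adjusted p = 0.0527). All 24 ribosome biogenesis genes rose, and so did 16 of 21 growth metabolism genes, 12 of 16 calcium and NFAT-induced genes and 11 of 17 surface molecules. Of the quiescence list 17 of 21 fell, as did 16 of 19 B cell identity genes, 8 of 11 MHC class II genes, 13 of 22 PKC and B cell receptor signalling genes, 13 of 22 interferon response genes and 8 of 10 NK cell markers. NF-kB targets split into 10 that rose, 5 that fell and 6 not called, cytokines into 8, 4 and 7, and immediate-early genes into 11, 8 and 8. Adjusted over the list alone, limma called 24 ribosome biogenesis, 18 growth metabolism, 15 NFAT, 15 surface, 20 quiescence, 18 B cell identity, 16 NF-kB, 13 cytokine and 21 immediate-early genes. With 1 residual degree of freedom, these p-values measure how alike the genotypes responded, and nothing in the labels says how many mice stand behind each array.

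The genotypes shared most of the response. Of the genes at least 2-fold higher, 1204 were so in both genotypes, where 198 would be shared by independent lists, and 1487 were at least 2-fold lower in both, against 283. A single gene, the microRNA Mir1951, passed 2-fold in opposite directions. Across genes, which are not independent replicates, the responses had a Pearson's r of 0.913 and a Spearman's rho of 0.867. Over the 3362 genes with a mean response of at least 1 in size, the slope of the Tilcara response on the wild-type response was 0.937. The Tilcara response was smaller in 2074 of them, with a median difference of −0.12 along the direction of the response. That median was −0.22 when genes were chosen by their wild-type response and −0.0055 when chosen by their Tilcara response.

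**Figure D2:**
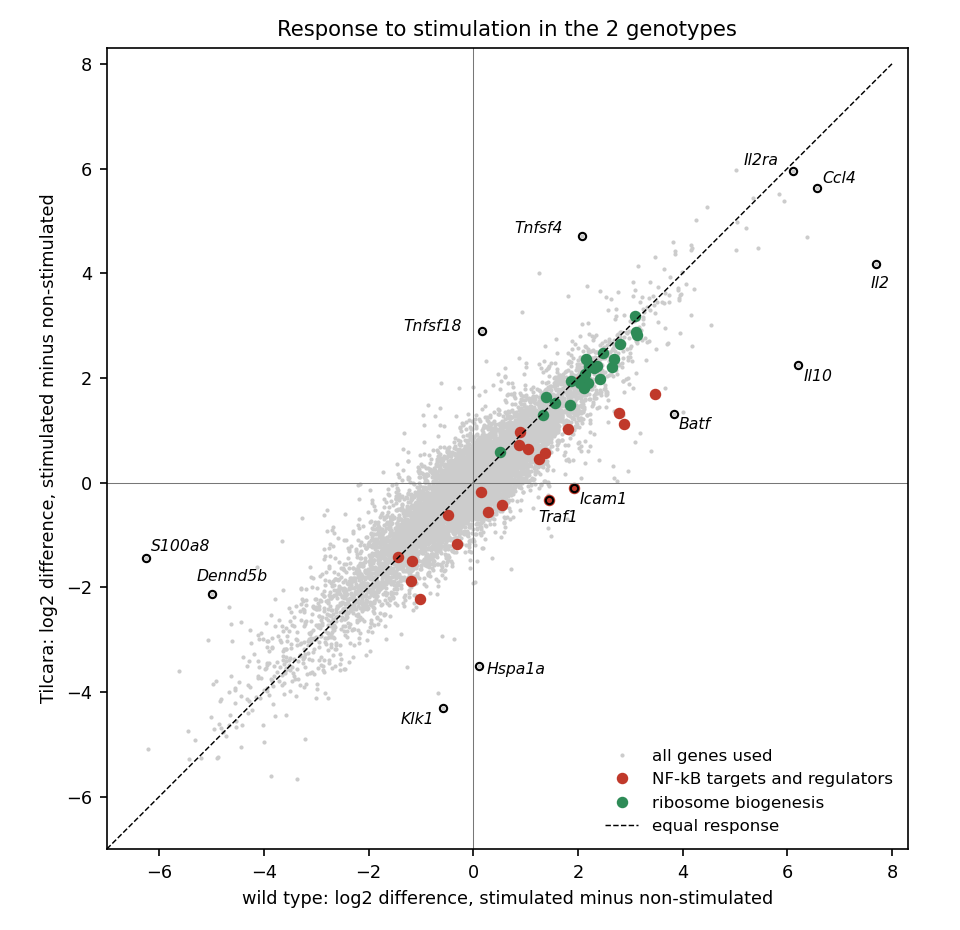
Log2 difference, stimulated minus non-stimulated, of each of 12456 genes in wild type (x axis) and Tilcara (y axis), 1 array per group, with 2 gene lists coloured and the line of equal response dashed. Ribosome biogenesis genes lie along the line, most NF-kB targets lie below it, and Il10 (6.21 and 2.25) and Il2 (7.70 and 4.17) lie far below it.

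Without stimulation, the genes with the largest decreases in Tilcara relative to wild type included transcripts of neutrophils and macrophages. S100a8 (probe set 17399823) was 36.5-fold lower, S100a9 11.5-fold, Lyz2 5.90-fold, AF067061 5.76-fold, the inflammatory cytokine Il1b 4.46-fold and the cysteine protease inhibitor gene Stfa2l1 3.81-fold. Higher in Tilcara were Klk1 (12.6-fold), Olfr825 (3.60-fold), Snhg18 (3.59-fold), the heat shock gene Hspa1a (3.51-fold), Coprs (3.15-fold) and Rasl2-9 (3.14-fold). Across genes, 53 were at least 2-fold higher and 82 at least 2-fold lower. Of these 135 genes, 66 lay in the lowest quartile of mean signal and 7 in the highest, so many sat near the floor; Olfr825 and Rasl2-9 did not exceed 3.95 in any array.

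B-1 cell genes were lower in non-stimulated Tilcara. B-1 cells are a B cell subset that makes natural antibodies, and 12 of the 14 measured genes of their list were lower, with a median of −0.57 below the random range of −0.18 to 0.18. Atxn1 (−1.09), Ptpn22 (−1.08), Tbx21 (−0.85) and Cd5 (−0.81) differed most. Plasma cell genes had a median of −0.17, with Jchain, for the chain that joins secreted immunoglobulins, 2.26-fold lower. Germinal centre genes (−0.25), cell cycle genes (−0.15) and immature B cell genes (−0.20) were also below the random range. Among the 8 main lists, immediate-early genes (0.15, with Fos at 0.76 and Spry1 at 0.73) and calcium and NFAT-induced genes (0.17, with Cd5 at −0.81 and Ndrg1 at 0.81) lay above it. Both of these medians fell inside the random range after cyclic loess, at 0.12 and 0.10. Ribosome biogenesis (0.01) and glycolysis (−0.05) lay inside it, as did NF-kB targets (−0.02, mean 0.04), surface molecules (0.01, mean −0.05), quiescence genes (0.07, mean −0.01) and cytokines (0.10, mean −0.05), where median and mean differ in sign; without a filter cytokines lay outside it, at 0.15. MHC class II genes (0.02) and marginal zone genes (−0.04) did as well, and so did B cell identity genes (0.01, mean −0.01) and PKC and receptor signalling genes (0.00, mean −0.04), again with differing signs.

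Markers of other cells differed beside these lists. The neutrophil list had a median of −0.45, the macrophage list −0.30, the T cell list −0.41 and the thymocyte list −0.36, each below the random range. Single T cell markers were Thy1, 3.63-fold lower in Tilcara, and Cd3g, 2.23-fold lower. Leaving out neutrophil and macrophage genes gave 53 genes higher and 78 lower. The markers of sex were alike in the 4 arrays, with Xist between 10.18 and 10.70 and the Y-linked genes Eif2s3y, Kdm5d and Uty between 1.61 and 2.33.

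After stimulation, the Tilcara array had lower signals of several cytokines than the wild-type array, and 6 of 21 NF-kB targets were at least 2-fold lower. As some T cell markers also differed by genotype, which of the sorted cells gave these transcripts cannot be told. Il10 was 10.4-fold lower and Il2 9.94-fold lower, followed by the AP-1 family factor Batf (6.88-fold), the chemokine Ccl22 (5.75-fold), the cytokine Il1a (5.69-fold) and Lrrc32, which encodes the TGF-beta anchoring protein GARP (5.51-fold). Higher in Tilcara were Crisp3 (7.46-fold), Dennd5b (7.38-fold), the TNF family ligands Tnfsf4, or OX40 ligand (6.91-fold), and Tnfsf18, or GITR ligand (6.06-fold), the adaptor Lax1 (6.15-fold) and Ifi208 (6.00-fold). Below the floor lay Il1a (2.40) and Ccl22 (3.77) in stimulated Tilcara, and Crisp3 (2.99), Dennd5b (2.82), Tnfsf18 (2.36) and Ifi208 (3.01) in stimulated wild type. For Dennd5b, the other probe set was higher by 1.14, less than the 2.88 of the one used. In total, 119 genes were at least 2-fold higher and 93 at least 2-fold lower, spread evenly over signal, with 50 in the lowest quartile and 55 in the highest.

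By list, 20 of 21 NF-kB targets were lower in stimulated Tilcara, with a median of −0.55 below all 10000 random lists. The survival gene Bcl2l1 was 4.58-fold lower, the adhesion molecule Icam1 3.45-fold, Traf1 3.25-fold and Tnfaip3 2.84-fold. Of the cytokines and chemokines, 18 of 19 were lower, with a median of −0.89; besides Il10, Il2 and Ccl22 these included Tnf (2.76-fold). Activation surface molecules had a median of −0.24, below the random range, with Cd274 2.63-fold lower and Il2ra differing by −0.10. Immediate-early genes were at −0.16, also below, where Junb (−0.91) and Spred1 (−0.81) differed most. Ribosome biogenesis genes were at −0.10, below a narrow random range of −0.06 to 0.13, with no member 2-fold different. Calcium and NFAT-induced genes had a median of −0.00 and a mean of −0.17; Il2 and Tnf were lower but Nr4a2 (1.01) and Cblb (0.68) higher. Glycolysis (0.02, with a mean of −0.01 of the other sign) and quiescence genes (0.08, with Txnip at 1.05) lay inside the random range.

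B-1 cell genes were lower in stimulated Tilcara too, with a median of −0.42 and 12 of 14 genes lower, led by Plscr1 (2.96-fold), Ctla4 (2.34-fold) and Zbtb32 (2.29-fold). Some B cell genes that were lower after stimulation in both genotypes stood higher in Tilcara: Fcrla by 3.69-fold, Cd79b by 3.05-fold and Bank1 by 2.98-fold. The identity list as a whole had a median of −0.00 and a mean of 0.28. MHC class II genes (0.15), PKC and receptor signalling genes (−0.02, with Rasgrp3 at 1.28) and interferon response genes (0.00, with Rtp4 at 1.15) lay inside the random range. Of the markers of other cells, S100a9 was 2.02-fold lower and Thy1 2.24-fold lower in Tilcara; the T cell list at −0.19 lay inside the random range. The neutrophil list, at −0.39, lay just inside a range of −0.39 to 0.28 and below its range without a filter, at −0.27. Erythroid markers, with 3 measured, lay at the lower limit of the random range, at −0.57.

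**Figure D3:**
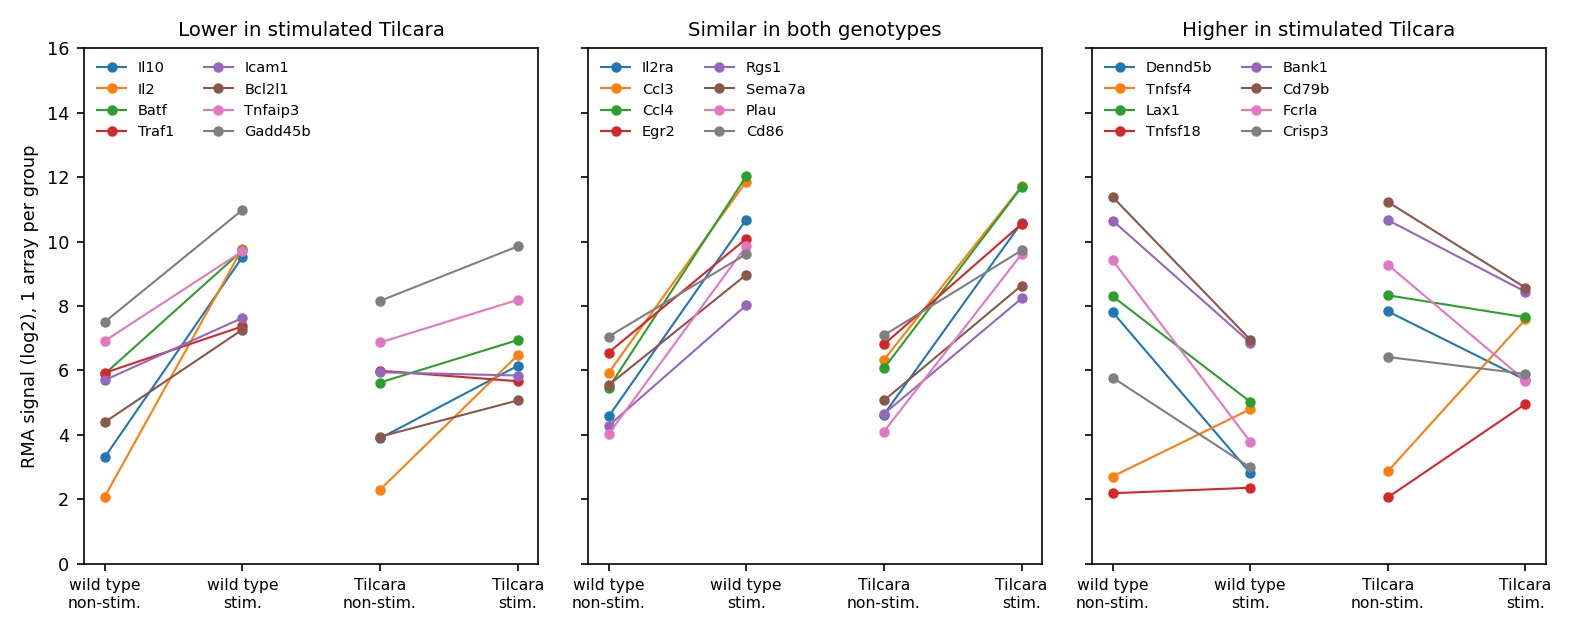
RMA signal (log2) of genes lower (left), similar (middle) or higher (right) in stimulated Tilcara than in stimulated wild type, 1 point per array, with lines joining the arrays of a genotype. Il10 reaches 9.52 in stimulated wild type and 6.14 in stimulated Tilcara, while Il2ra reaches 10.68 and 10.58.

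**Figure D4:**
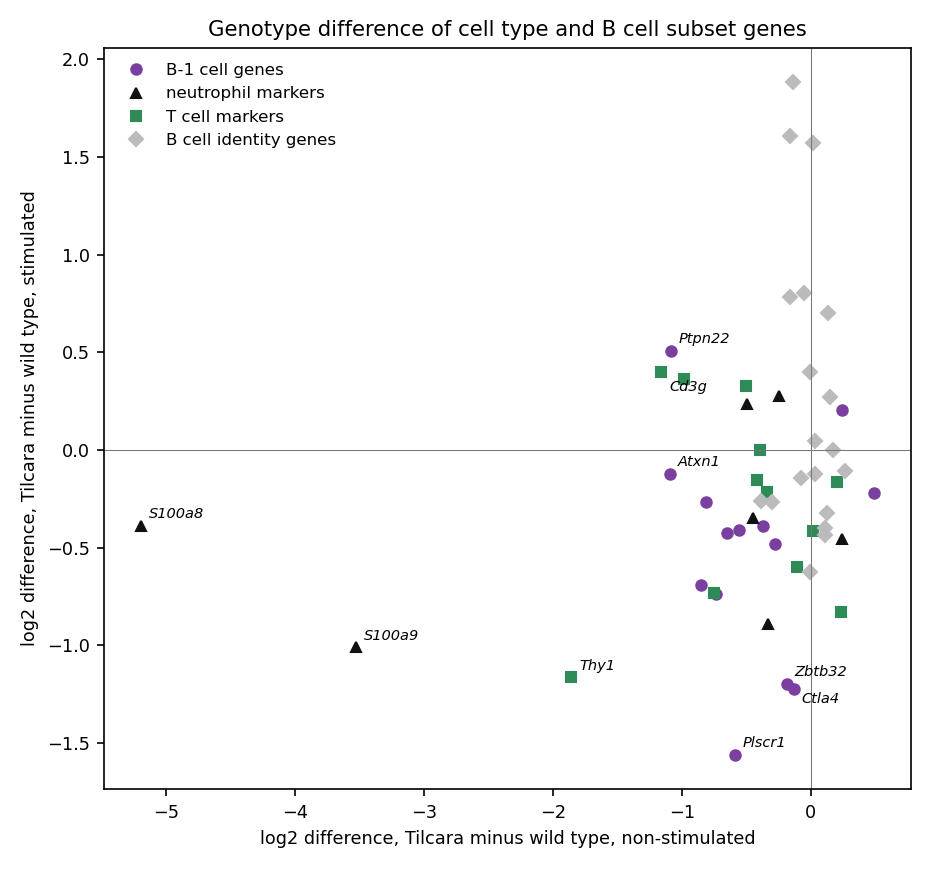
Log2 difference, Tilcara minus wild type, of single genes of 4 lists without stimulation (x axis) and with it (y axis), 1 array per group. B-1 cell genes lie mostly below 0 on both axes, and S100a8 and S100a9 lie at −5.19 and −3.52 on the x axis.

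Setting both responses against each other, Il10 had the largest shortfall in Tilcara, its response being 15.6-fold smaller, with Il2 at 11.6-fold; non-stimulated Il2 (2.08 and 2.30) and wild-type Il10 (3.31) lay below the floor. Klk1 (13.3-fold), Hspa1a (12.2-fold) and Hspa1b (10.2-fold) were also among the largest, each with a higher non-stimulated signal in Tilcara and Klk1 with signals below the floor in the other 3 arrays, and the transcriptional regulator Id2 followed (6.93-fold). The largest differences the other way were those of S100a8 (27.9-fold), which rests on its signal in the non-stimulated wild-type array, Dennd5b (7.27-fold), Emb (6.68-fold), Tnfsf18 (6.63-fold), Tnfsf4 (6.18-fold) and Lax1 (6.03-fold). Across genes, 289 responses were at least 2-fold higher in Tilcara and 206 at least 2-fold lower, and with no residual degrees of freedom no gene could be tested.

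NF-kB targets had a median difference of responses of −0.80, below all 10000 random lists, and the difference was negative for 19 of 21. The random lists were matched on signal and not on size of response, so they do not show how often lists of equally responsive genes would lie so low. Members with a negative difference were of both kinds. The 19 include genes such as Cd40 (−1.01 in wild type and −2.22 in Tilcara) and Birc3 (−1.19 and −1.88) that were lower after stimulation, and more so in Tilcara. Of the 10 that were at least 2-fold higher in wild type, all 10 responded less in Tilcara and 5 still passed 2-fold there. Choosing genes by their wild-type response favours a smaller Tilcara response by regression to the mean. Of all 1666 genes chosen so, 1219 responded less in Tilcara and 1204 still passed 2-fold. Icam1 (−2.03), Gadd45b (−1.79), Traf1 (−1.77) and Bcl2l1 (−1.75) differed most, while Rel differed by 0.06. Cytokines and chemokines were at −0.71, with 18 of 19 negative, among them Ccl22 (−2.37), Lif (−1.58) and Tnf (−1.58), and the exception Il1b at 1.58; of the negative ones Ltb (−4.02 and −4.62) and Il12a (−1.93 and −2.31) were lower after stimulation in both genotypes. Of 12 cytokine genes at least 2-fold higher in wild type, 8 were so in Tilcara, a share near that of all genes (1204 of 1666). Immediate-early genes were at −0.25, below the random range, with Fosb at −1.29 and Junb at −1.18. Quiescence genes were at 0.21, above it, with Bach2 (1.08) and Txnip (0.93), but at 0.02 and inside the range when probe sets were averaged. Calcium and NFAT-induced genes were at 0.00 with a mean of −0.23, surface molecules at −0.16, ribosome biogenesis at −0.11 and glycolysis at 0.09, all inside it. Lists of other cells also stood apart here, neutrophil markers at 0.53 and macrophage markers at 0.41, and the T cell genes Cd3g (1.56), Cd8b1 (1.35) and Cd28 (−1.06), as well as Lyz2 (1.79), S100a9 (2.51), Cox6a2 (−1.51) and Pacsin1 (1.06), differed by at least 2-fold.

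As a whole, stimulation separated the arrays far more than genotype. With each contrast scaled to carry equal noise, the SD across genes was 1.09 for stimulation, 0.25 for genotype and 0.24 for the difference of responses, and stimulation held 91.0% of the summed variance. The genotype contrast was thus barely larger than the difference of responses, which holds the array noise, with 53 against 48 genes at an absolute contrast of at least 1. The genotype differences of the 2 states were nearly unrelated across genes, with a Pearson's r of 0.063. Array noise alone would also give an r near 0, so this does not show genotype effects that depend on the state. Ifi208 and Snora2b were at least 2-fold higher in Tilcara in both states, and Havcr1, Ifitm2, Jchain, S100a9 and Thy1 at least 2-fold lower in both. Hspa1a, Hspa1b, Emb, Mir3473c and Trim43c passed 2-fold in opposite directions, but the other probe set of Emb passed in neither state (−0.73 and −0.00) and had a difference of responses of 0.73. For the main effect of genotype limma called 0 genes; 667 had an unadjusted p under 0.05, and the lowest adjusted p was 0.866. As the difference of responses counts as error in that fit, a genotype effect seen in only 1 state cannot pass easily.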

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

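Among the tests in this part, those on the strength of the whole culture's response and on neutrophils as a source of the NF-kB and B-1 differences were chosen after their results had been seen, and the second gene lists were written after the comparisons had been seen.

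Among the 8 main lists and the 6 genes with the largest difference of responses in each direction, single members of lists not counted, 3 had responses of opposite sign in the genotypes, each from 1 array per group, and the difference was not tested. The median of the NF-kB list was 0.90 in wild type and −0.10 in Tilcara (inside the random range, mean 0.00), a difference of responses of −0.80. The immediate-early list was at 0.28 and −0.06, both inside the random range and the latter with a mean of 0.27, with a median difference of −0.25. Hspa1a was at 0.11 and −3.50, a difference of −3.60, where the wild-type value is close to 0.

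Weaker induction of NF-kB targets in Tilcara was the first pattern weighed. Ribosome biogenesis, a list chosen with its values already known, had a median response in Tilcara that was 0.971 of that in wild type. This argues only against a response weakened in equal proportion for all genes. Over all stimulated genes the slope was 0.937, and a weaker response of other programmes was not excluded. After cyclic loess, which started from normalized values, the NF-kB list's difference was −0.82. A remaining signal-dependent shift between the arrays thus does not account for it, but the original normalization was not tested. Neutrophil transcripts in the non-stimulated wild-type array do not enter the difference between the stimulated arrays, which was −0.55; in wild type and Tilcara there, S100a8 (2.75 and 2.36), S100a9 (3.48 and 2.47) and Lyz2 (3.28 and 2.52) lay below the floor of 3.83, although the second neutrophil list differed by −0.29. A second list of 24 measured NF-kB targets also had a negative median difference of responses (−0.30, random range −0.16 to 0.14), though its mean was −0.10, its wild-type response was inside the random range (median 0.09) and 9 members went the other way, Csf1 by 1.75. Lower NF-kB activity in the PKCbeta mutant may be a candidate explanation. With 1 array per group, however, a difference between 2 cultures unrelated to genotype cannot be told apart from it. A different share of T cells among the sorted cells was not tested as a source. Between the stimulated arrays the T cell list was at −0.19, inside its random range, but its member Thy1 was at −1.17.

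The second pattern was the neutrophil transcripts in the non-stimulated wild-type array, with S100a8 at 9.0, S100a9 at 7.61 and Lyz2 at 5.99 against 3.81, 4.09 and 3.43 in Tilcara. A remaining signal-dependent shift between the arrays does not account for them, as the S100a8 difference was −5.14 after cyclic loess. That step started from normalized values and could hardly move a single gene so far, so the original normalization was not tested. For neutrophils among the sorted cells, which a B220 gate would be meant to remove, the prediction written beforehand failed: the second neutrophil list had a median of −0.11, inside the random range of −0.25 to 0.22, while between the stimulated arrays it was −0.29, below −0.24 to 0.24, so its difference is not confined to the non-stimulated arrays. That test is read as undecided, a reading adopted after its result was seen, because 25 of the list's 34 genes lay below the signal floor and Pglyrp1 (8.20 and 8.56) and Wfdc21 (7.24 and 7.53) were high in both arrays; without the floor, 23 of 34 genes were lower and the median was −0.18, below the random range. In the list fixed beforehand 13 of 14 genes were lower. Ngp (3.81), Camp (3.40) and Ltf (3.36) stayed near the floor even in wild type, and signals this low speak neither for nor against neutrophils. Neutrophils among the sorted cells, RNA from other cells and a difference between mice all remain possible sources.

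The third pattern was the lower B-1 cell genes in both Tilcara arrays. Neutrophils in the non-stimulated wild-type array do not enter the difference between the stimulated arrays, where the B-1 median was −0.42. They may still account for the difference without stimulation, on which the stimulated arrays cannot decide. In both stimulated arrays S100a8, S100a9 and Lyz2 lay below the floor, but such low signals do not show that neutrophils were absent. Of the 14 measured genes 9 are also used by myeloid or T cells, and the other 5 had a median of −0.28 without stimulation, inside the random range of −0.35 to 0.31, and −0.48 with it, below the range. A second B-1 list was at −0.10, inside the random range, and at −0.41, below it, so a lower share of B-1 cells may fit the stimulated arrays and is undecided without stimulation. The T cell (−0.41), macrophage (−0.30) and neutrophil (−0.45) lists lay below their random ranges without stimulation and inside them with it. With stimulation the neutrophil list, at −0.39, was only just inside, and it lay below its range without a filter on low signals (−0.27). The second neutrophil list, at −0.29, also lay below its range with stimulation. With mixed results in both tests, fewer B-1 cells, a difference in activation of the same cells and fewer T or myeloid cells cannot be told apart.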

How the results depend on the processing

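The alternatives in this part were planned, except the counts without neutrophil and macrophage genes, which were chosen after the results were seen. No result reversed its direction in the listed alternatives, but for genes that were lower among those chosen by the Tilcara response the median difference of responses was 0.0070, opposite in sign to the −0.12 reported. All 120 values of named genes under other settings stayed within the limits set, 60 after cyclic loess and 60 with probe sets averaged. Averaging leaves a gene with 1 probe set unchanged, as most named genes were, so this says little about them. Of the values of the 8 main lists, 193 of 200 kept their side of the random range. Among the other lists 489 kept it, 16 moved outside it and 15 moved inside. The median difference of NF-kB targets between the stimulated arrays ranged from −0.59 to −0.52 and the difference of responses from −0.82 to −0.80. With a threshold of 1.5-fold, which by construction counts more genes, the numbers higher and lower were 2951 and 3083 for stimulation in wild type, 2766 and 2834 in Tilcara, 413 and 422 for genotype without stimulation, 584 and 455 with it, and 1091 and 1003 for the difference of responses. A filter at the 75th percentile, which tests fewer genes, gave 25 and 28 for genotype without stimulation, 78 and 60 with it, 132 and 99 for the difference of responses, and 34 genes for the genotype contrast in place of 53. Without a filter, 331 responses were lower in Tilcara. The NF-kB list's wild-type response was 0.72 without shared members, just inside the random range. After cyclic loess the non-stimulated genotype medians of immediate-early (0.12) and NFAT genes (0.10) moved inside the random range, as did NFAT genes without a filter (0.12), while without a filter cytokines moved outside it in the Tilcara response (0.31) and the non-stimulated genotype difference (0.15). Quiescence genes had a difference of responses of 0.021 when probe sets were averaged. The median difference of responses along their direction was −0.22 over genes chosen by the wild-type response and −0.0055 over genes chosen by the Tilcara response, which the choice itself produces in part by regression to the mean. For the other shifts the cause was not tested. limma called 2460 to 2951 genes that rose and 2564 to 3225 that fell with stimulation, and 0 for genotype in each alternative, with 670 to 1138 genes at an unadjusted p under 0.05. The SD of the contrast for the difference of responses, scaled to carry the same noise as the contrasts for stimulation and genotype, was 0.27 in the lowest quartile of signal and 0.19 in the highest, so low signals limit the smaller differences most. No paired analysis was possible because the sources used here name no animal shared between arrays; the limma fit compares stimulation within genotype only. With 1 array per group, no replicate could be left out.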

Other observations

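All tests of the hypothesis in this part were chosen after the comparisons had been seen, although its prediction was written before the list's values were read together.

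Genes of the unfolded protein and amino acid stress response had median responses of 1.14 in wild type and 1.16 in Tilcara, and limma called 10 of 15 that rose. Marginal zone B cell genes had medians of −0.81 and −0.67, with Notch2 at −2.89 and −2.72, whereas the tetraspanin gene Cd9 was higher by 2.38 and 1.71. The other probe set of Cd9 differed less, by 0.85 and 0.26. Immature B cell genes were at −0.98 and −0.45, and their difference of responses of 0.62 lay above the random range, with Myb at 1.59 and Sox4 at 0.86. Cell cycle genes had medians of 0.28 and 0.36, led by the replication helicase gene Mcm6 at 1.44 and 2.03, germinal centre genes 0.27 and 0.69, and plasma cell genes −0.17 and −0.02. For p53 and apoptosis genes the medians were 0.12 and 0.00 while the means were −0.08 and −0.13, of the other sign, although Bcl2l11 was higher by 2.14 and 2.06 and Cdkn1a by 2.02 and 2.05. Housekeeping genes had medians of 0.02 and −0.00, the latter with a mean of 0.24, but Actb differed by −0.50 and −1.52 and Tfrc by 2.75 and 2.60. Erythroid markers, with 3 measured, were at 0.31 and −0.07 (mean in Tilcara 0.34), dendritic cell markers at −0.40 and −0.34, and thymocyte markers, with 4 measured, at −0.55 and 0.28 (mean in Tilcara −0.13).

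Of the heat shock list, Hspa1a and Hspa1b had the largest differences of responses, −3.60 and −3.35, followed by Hsph1 at −1.18, while Dnajb1 (−0.30), Hspb1 (−0.39) and Bag3 (0.43) differed little. Hspa1a read 7.79 and 9.60 in the non-stimulated wild-type and Tilcara arrays and 7.89 and 6.10 in the stimulated ones, Hspa1b 9.15 and 10.71 against 8.48 and 6.68, and Hsph1 6.05 and 6.88 against 7.81 and 7.46. The constitutive Hspa8 lay between 11.73 and 12.01. The heat shock list had a median response of 0.16 in both genotypes, with a mean of −0.57, of the other sign, in Tilcara. Klk1 stood at 6.41 in the non-stimulated Tilcara array and between 2.09 and 2.75 in the other arrays, whereas the dendritic cell list that holds it had a median genotype difference of 0.06. Probe sets without a single symbol that reached the floor were at least 2-fold higher in 1377 and lower in 1624 cases in the wild-type response, and 1465 and 1312 in Tilcara.

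Il2, Stat5a and Cish, a target of the transcription factor STAT5 downstream of interleukin-2, were all lower in stimulated Tilcara, Stat5a at 5.01 against 7.39 and Cish at 5.76 against 8.07, while Il2ra was alike. One hypothesis is that STAT5 targets respond less in the Tilcara culture. A list of 22 measured STAT5 targets had a median difference of responses of −0.24, below the random range of −0.18 to 0.18, with Socs3 at −2.31 and Furin at −1.23 but Myb at 1.59, which is consistent with it. However, 9 of the 25 genes written for the list belong to other lists, and without them 14 measured genes had a median of −0.21, inside the random range of −0.23 to 0.23; between the stimulated arrays these 14 were at −0.18, below −0.14 to 0.19, with 11 lower. Several members, such as Socs3, Pim1 and Lif, answer to other factors as well, so the list may not separate STAT5 from NF-kB. Which of the sorted cells gave the Il2 and Cish transcripts cannot be told either, because some T cell markers also differed by genotype.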
